A study of Mus musculus with 6 samples.

How the data were processed

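The samples are retinal ganglion cells (RGCs) of wild-type C57 mice at embryonic day 18 (E18), postnatal day 5 (P5) and 8 weeks of age (Adult), with 2 libraries per age and 6 in all. Per the labels' protocols, the cells were isolated by panning on antibody to Thy1, an antigen of ganglion cells, after other antibodies had removed macrophages; the sample protocol also names removal of amacrine cells, which the series description does not. Libraries were made from polyA-selected RNA, and paired reads of 100 bases were sequenced.

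The values are isoform FPKM (fragments per kilobase of transcript, scaled to mapped fragments) as deposited by the authors. Per the submitters' processing notes, HISAT2 mapped the reads to mm10 (GRCm38), and Cufflinks and Cuffdiff gave the abundances; no versions are stated, and neither is any scaling between libraries. The table lists 50829 isoforms under 17027 gene symbols. The highest value of every isoform was at least 1.00 FPKM, and 0.0001 stands in place of 0. The columns of the P5 libraries carry one shared header, so these libraries are called a and b here, while those of E18 and Adult keep the replicate numbers of their labels. Isoform lengths served only for fragment shares and for the tests on transcript length. A further 9 columns with per-sample values were not used here. FPKM carry no read counts, so the depth of each library and the counting error of each gene are unknown, and precision rests on the spread between libraries.

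Positions and gene types were taken from the GRCm38 gene annotation supplied with the genome. Of the isoforms listed as equal to an annotated transcript, 97.5% carried an identifier of that annotation, all of these lay inside the listed locus (100.0%), 87.5% had the same symbol and 94.5% had a length within 10 bases. Genes are therefore named by the symbols of the deposited table.

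Isoform FPKM were summed per gene symbol, and log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with a trend of the variance on expression). Age was the factor, all 6 libraries shared one estimate of the spread, and no replicate block was used. A gene or isoform was tested if its mean over the 6 libraries reached 1 FPKM, which left 14390 genes and 34941 isoforms. The fit had 3 residual degrees of freedom and a prior of 3.26 for genes and 2.88 for isoforms. The 3 comparisons were P5 against E18, Adult against P5 and Adult against E18. Tests were two-sided, adjusted by Benjamini-Hochberg within each comparison, and called at an adjusted p under 0.05. The scale of log2(FPKM + 1) understates the fold change of genes with low values. Means are given ± SD with n = 2 libraries, and intervals of a log2 change are 95% intervals from limma. In the tests on explanations, intervals are instead 95% intervals from resampling genes. Nothing in the labels says whether the 2 libraries of an age came from separate animals or litters, so all p-values measure only the spread between these samples.

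Before the data were examined, 42 gene lists, the tests, the alternatives and the rule for named genes were fixed. The named genes are Rpl7 and Rpl7a, the 10 largest rises and 10 largest falls of each comparison, and members of each list. The largest changes were drawn from called genes with groups that did not overlap and at least 10 FPKM in the higher group, without predicted genes (Gm and Rik symbols), microRNAs and small RNA symbols. From each list came the 4 members with the smallest p and the 2 with the highest level. The isoforms of Rpl7 and Rpl7a were added. Some genes that meet this rule are not reported here. A gene named outside this rule is described as chosen after its values were seen. Each list was compared with all other tested genes by camera (limma, preset correlation between genes of 0.01) and tested by itself with fry. Lists with fewer than 3 tested members had no set test, which left 34 lists and 102 tests, adjusted together by Benjamini-Hochberg. Of these, camera called 53 and fry called 62. With the correlation estimated from the data, camera called 0, with 9 under an unadjusted p of 0.05, so no camera call in the text holds with an estimated correlation. In that setting camera tests on the 3 residual degrees of freedom of the fit, which leaves little power over 102 tests. A call lost there therefore does not tell whether correlation between genes had made it. fry asks whether the genes of a list move, on balance, one way and does not compare the list with other genes.

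The fit was tested on simulated data with normal noise in which 100 genes of each comparison changed by a log2 of 1 and another 100 by 2. The fit recovered 50% and 85% of them between E18 and P5, 45% and 87% between P5 and Adult, and 59% and 88% between E18 and Adult, with 6 false calls among 141, 12 among 144 and 8 among 155. The changed genes were drawn from those with an E18 mean of log2(FPKM + 1) above 2, and all other genes stayed unchanged. These rates therefore do not carry over to genes of low level, nor to the Adult comparisons, in which most genes were called. Alternatives for the values covered pseudocounts of 0.1 and 0.01, no filter and a mean of at least 5 FPKM, rescaling every library to one total (TPM), equal medians and quantile normalization. Alternatives for the fit covered one without the trend, robust variances, only the 4 libraries of the ages compared, a replicate block, each library left out in turn, a 2-fold minimum, the most abundant isoform of each gene and the estimated correlation. A rescaling to protein-coding genes and a fit without genes listed at 0 in an age were added after seeing the data. That fit left out only genes listed at 0 in both libraries of an age with a mean of at least 10 FPKM at another age. For reads that could be shared with pseudogenes, the share of 31-base stretches of each gene's main isoform found in 13607 annotated pseudogene transcripts was computed. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.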

Results

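RGCs isolated at E18, P5 and 8 weeks of age were compared by the FPKM of 2 libraries per age. The Adult libraries stood apart from those of both younger ages. Across the 14390 tested genes, Pearson's r of log2(FPKM + 1) was 0.978 between the E18 libraries, 0.975 between the P5 libraries and 0.941 between the Adult libraries. It lay between 0.941 and 0.964 for E18 with P5 and between 0.719 and 0.763 for Adult with the younger ages. Genes are not independent replicates, and no p is given. The markers of RGCs had median levels of 89.9 and 97.2 FPKM in the E18 libraries, 85.5 and 94.4 FPKM at P5, and 12.7 and 8.43 FPKM in Adult. Markers of rod photoreceptors had medians of 0.386 and 0.116 FPKM at E18, 0.124 and 0.144 FPKM at P5, and 182 and 24.4 FPKM in Adult replicates 1 and 2.

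The Adult libraries also differed in the make-up of their totals. Small RNAs took 55.5% and 59.9% of all FPKM in Adult, against 24.3% and 24.2% at E18 and 19.74% and 20.03% at P5. Rn7sk, a small nuclear RNA made by RNA polymerase III, was listed at 0 at E18 and P5 and at 186777 and 213874 FPKM in Adult, so no fold change is given. By FPKM times length, protein-coding genes held 83.3% and 79.96% of the estimated fragments in Adult and between 94.3% and 94.8% in the younger libraries. Cytosolic ribosomal protein genes held 2.07% and 1.98% of the estimated fragments at E18, 1.44% and 1.45% at P5, and 0.665% and 0.604% in Adult. The median log2 change of all tested genes was -0.03 from E18 to P5, -0.07 from P5 to Adult and -0.11 from E18 to Adult. Rescaling to TPM moved these medians to 0.08, -0.76 and -0.68, and rescaling to protein-coding genes moved them to 0.02, 0.19 and 0.21. Where a scaling moved a gene family, its median is therefore also given relative to that of all genes.

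Rpl7 and Rpl7a, which encode proteins of the large ribosomal subunit, were lower at P5 than at E18, and so were most cytosolic ribosomal protein genes. Rpl7 had 496 ± 29.1 FPKM at E18 and 294 ± 10.1 FPKM at P5 (1.68-fold lower, log2 change -0.75, SE 0.09, interval -0.98 to -0.52, limma adjusted p = 0.0124). Rpl7a had 185 ± 2.10 FPKM at E18 and 132 ± 3.17 FPKM at P5 (log2 change -0.49, SE 0.09, interval -0.69 to -0.28, limma adjusted p = 0.0255). Both P5 libraries lay below both E18 libraries for each gene. The genes were chosen because the series title names them as lower with development, so they are not independent evidence of direction. Rpl7 lies on the minus strand of chromosome 1 (16101295 to 16104662) and Rpl7a on the plus strand of chromosome 2 (26910764 to 26913318) in GRCm38. Annotated pseudogenes hold 61.3% of the 31-base stretches of Rpl7 and 85.0% of those of Rpl7a, so reads of each gene may be shared with pseudogenes. How many reads were shared was not measured. With 1 library left out, Rpl7 had an adjusted p of 0.108 without E18 replicate 1, 0.0875 without E18 replicate 2 and 0.0812 without P5 library a. The adjusted p of Rpl7a was 0.190, 0.144 and 0.0965 without the same libraries, 0.0553 without P5 library b, and 0.0506 and 0.0504 without Adult replicates 1 and 2, with lower values at P5 throughout.

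**Figure D1:**
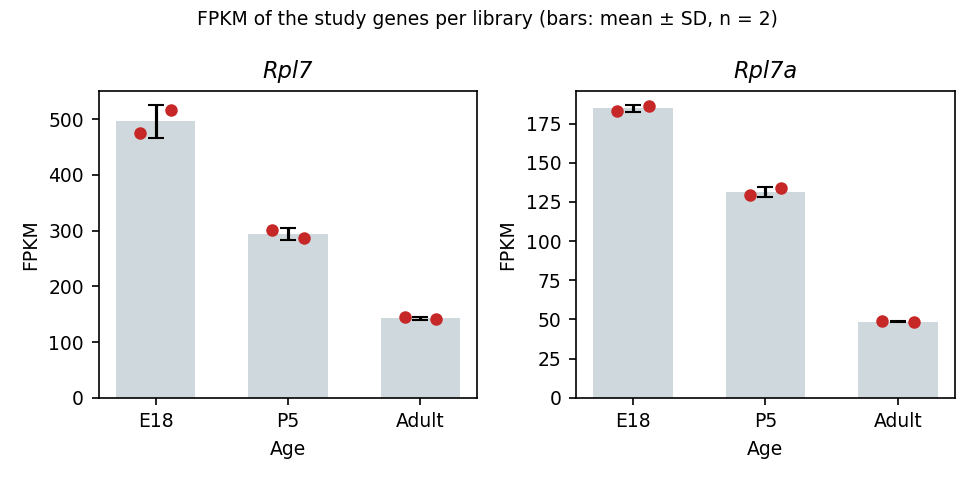
FPKM of Rpl7 and Rpl7a (vertical axes, from 0) at E18, P5 and Adult; points are libraries, bars are means and error bars are SD (n = 2). Rpl7 went from 496 to 294 and 143 FPKM and Rpl7a from 185 to 132 and 48.6 FPKM.

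Of the 46 tested proteins of the cytosolic large subunit, 30 fell from E18 to P5, none rose and 16 were not called (40 fell when adjusted over the list alone; median log2 change -0.47, or -0.44 relative to all genes). Of the 33 small subunit proteins, 23 fell and 10 were not called (30 fell when adjusted over the list alone; median -0.57, or -0.54 relative to all genes). Rpl34 went from 272 ± 0.468 to 163 ± 0.998 FPKM (log2 change -0.74) and Rplp0 from 516 ± 9.01 to 333 ± 21.0 FPKM (-0.63). Rpl41, with the highest level of the large subunit, had 1002 ± 14.5 and 762 ± 11.7 FPKM and was not called (adjusted p = 0.0827). All 79 log2 changes of the ribosomal protein genes were negative, between -0.82 and -0.11, and Rpl7 ranked 3 and Rpl7a 44 from the lowest. camera placed both lists below other genes (adjusted p = 2.01e-17 and 5.36e-15), a call lost in both with an estimated correlation (adjusted p = 0.354). fry gave adjusted p = 0.00372 and 0.00649. The median of the RGC markers was 0.05 in the same comparison, with 5 risen and 1 fallen of 25, while progenitor markers and cell cycle genes had medians of -0.89 and -0.54 (-0.05 and -0.06 without E18 replicate 1). Without E18 replicate 1, E18 replicate 2 or P5 library a, none of the 79 genes was called. Without P5 library b, 5 large and 1 small subunit genes fell, and without either Adult library, 10 and 15 fell. The medians stayed between -0.48 and -0.47 for the large and between -0.57 and -0.54 for the small subunit in these fits. With TPM, 13 large and 11 small subunit genes fell, and with quantile normalization 10 and 11.

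**Figure D2:**
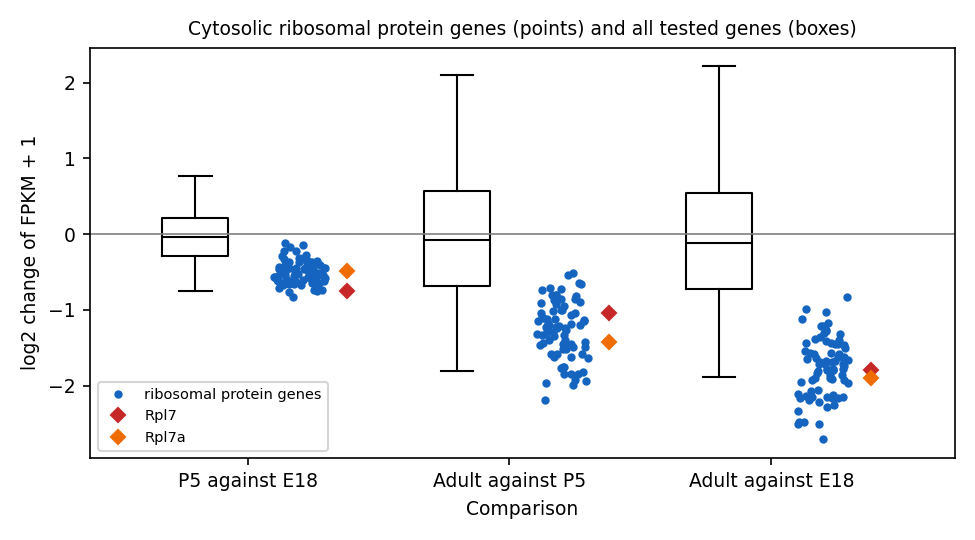
Log2 change of FPKM + 1 (vertical axis) for the 79 cytosolic ribosomal protein genes and all 14390 tested genes in the 3 comparisons. Points are the 79 genes, with Rpl7 and Rpl7a as diamonds. Boxes give the median and quartiles of all tested genes, and whiskers span a wider range of them. The median of the 79 genes was -0.51 from E18 to P5, -1.23 from P5 to Adult and -1.73 from E18 to Adult, and all 79 values were negative in each.

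Genes of synaptic transmission and excitability were among those that rose between E18 and P5. Among voltage-gated sodium and potassium channels, 10 of 28 rose and none fell (14 rose when adjusted over the list alone; median 0.52). Kcnip4, a modulator of potassium channels, went from 4.36 ± 0.252 to 23.9 ± 2.81 FPKM (log2 change 2.21) and the sodium channel Scn1a from 7.60 ± 1.19 to 27.4 ± 0.989 FPKM (1.73). Postsynaptic receptors and scaffolds had 10 risen and 1 fallen of 37 (15 and 1 over the list alone; median 0.50), among them the glycine receptor subunit Glrb (9.86 ± 1.78 to 48.8 ± 18.3 FPKM, 2.16). Of 28 genes of synaptic vesicles and active zones, 6 rose (8 over the list alone; median 0.24), including Snap25 (391 ± 53.0 to 796 ± 89.2 FPKM, 1.03) and Syp (93.5 ± 5.26 to 164 ± 6.89 FPKM, 0.81). Of 9 chloride transporters and calcium buffers, 3 rose (4 over the list alone; median 0.56), including the chloride extruder Slc12a5 (18.3 ± 2.43 to 47.1 ± 9.64 FPKM, 1.31). camera called these lists (adjusted p = 1.49e-07, 5.41e-07, 0.00232 and 0.00214), calls lost with an estimated correlation (adjusted p = 0.354 in all 4). Without E18 replicate 1, E18 replicate 2, P5 library a, P5 library b, Adult replicate 1 and Adult replicate 2 in turn, 0, 2, 0, 5, 6 and 6 channel genes and 0, 0, 0, 5, 5 and 5 postsynaptic genes rose. Without the same first 3 libraries no gene of the vesicle and chloride lists rose, and without P5 library b 2 vesicle genes did. With TPM, 16 channel genes rose and the vesicle genes had a median of 0.37. Relative to all genes, these lists had medians of 0.56 and 0.27 as deposited and 0.60 and 0.30 with TPM.

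From E18 to P5, 28 of 33 genes of axon growth and all 21 of cholesterol synthesis had negative changes, though most were not called. Of 33 axon growth and regeneration genes, 6 fell and 1 rose (10 and 2 when adjusted over the list alone; median -0.28). Sox11, a transcription factor of young neurons, went from 126 ± 2.20 to 37.3 ± 6.48 FPKM (log2 change -1.74), Socs3, an inhibitor of cytokine signaling, from 16.4 ± 1.20 to 3.12 ± 0.163 FPKM (-2.08), and Klf9, a repressor of axon growth, from 2.88 ± 0.740 to 8.83 ± 1.35 FPKM (1.35). In cholesterol synthesis, 7 of 21 genes fell (15 over the list alone; median -0.82), including Hmgcs1 (884 ± 123 to 409 ± 146 FPKM, -1.15). None of the 21 was higher in E18 replicate 1 than in replicate 2 (median difference -0.29 against -0.04 for all genes), and the list had medians of 46.7 and 36.0 FPKM in P5 libraries a and b. camera called both lists (adjusted p = 0.00114 and 5.41e-07), calls lost with an estimated correlation (adjusted p = 0.359 and 0.504). Nuclear genes of oxidative phosphorylation had 5 risen of 76 (2 over the list alone; median 0.26), such as Ndufa5 (87.7 ± 5.97 to 153 ± 14.1 FPKM, 0.80), with a camera adjusted p of 5.04e-10 and an adjusted p of 0.517 with an estimated correlation. Of the oxidative phosphorylation genes, 23 rose with TPM, 12 with quantile normalization and 16 with protein-coding genes only, while their median relative to all genes stayed between 0.29 and 0.32. Only 3 axon growth genes fell and 3 rose with TPM (median -0.16, or -0.24 relative to all genes against -0.25 as deposited) and with quantile normalization, and 4 cholesterol genes fell with equal medians and 3 with quantile normalization. Without E18 replicate 1, E18 replicate 2 or P5 library a, 0, 1 and 0 axon growth genes fell, no cholesterol gene fell and no oxidative phosphorylation gene rose. Without P5 library b these numbers were 4, 0 and 3, and without either Adult library 2, 2 and 2.

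Cell cycle genes had a median of -0.54 (Mcm7 fell, 1 of 19; camera adjusted p = 0.0240, and adjusted p = 0.721 with an estimated correlation). Markers of retinal progenitors and neuroblasts had a median of -0.89 (2 fell and 1 rose of 22; camera adjusted p = 0.00903, and adjusted p = 0.621 with an estimated correlation). E18 replicate 1 stood apart in both lists. All 19 cell cycle genes and 18 of the 22 progenitor markers were higher in it than in replicate 2, with median differences of 0.95 and 1.39 against -0.04 for all genes. Without E18 replicate 1 the medians of the comparison were -0.06 and -0.05, and without replicate 2 they were -1.008 and -1.57, with 3 and 5 genes fallen. With 1 library left out, Mcm7 was called without P5 library b and in no other such fit.

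Across all genes, limma called 795 genes higher and 712 lower at P5 than at E18 (1507 of 14390; Benjamini-Hochberg), and 281 isoforms higher and 288 lower (758 and 307 with TPM). Among genes not listed at 0 at either age, the largest rises were those of Hspb1, a small heat shock protein (2.95 ± 0.440 to 37.5 ± 20.2 FPKM, log2 change 3.18), Sparcl1 (6.64 ± 1.05 to 65.7 ± 13.9 FPKM, 3.12) and Lynx1, a modulator of nicotinic receptors (2.37 ± 0.144 to 28.7 ± 10.03 FPKM, 3.10). Malat1 was listed at 0 at E18 and at 1408 ± 193 FPKM at P5. The largest falls among them included those of the lactate transporter Slc16a3 (69.8 ± 11.8 to 8.00 ± 1.96 FPKM, -2.98) and Cdkn1c, an inhibitor of cyclin-dependent kinases (42.8 ± 0.539 to 5.30 ± 0.715 FPKM, -2.80). BX000537.1 was listed at 0 at P5. The number of called genes depended on single libraries. It was 28 without E18 replicate 1, 117 without E18 replicate 2, 10 without P5 library a, 579 without P5 library b, and 640 and 642 without Adult replicates 1 and 2. The number of called isoforms was 4, 8, 3, 18, 5 and 5 in the same order. With TPM 1479 genes rose and 466 fell, and with protein-coding genes only 1118 rose and 611 fell.

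From P5 to Adult, all 79 genes of the cytosolic ribosomal subunits fell, together with most genes of axon growth and most RGC markers, while most markers of photoreceptors, bipolar cells, amacrine cells and Müller glia rose. Rpl7 fell from 294 ± 10.1 to 143 ± 2.78 FPKM (2.05-fold, log2 change -1.04, SE 0.09, interval -1.27 to -0.81, limma adjusted p = 0.000264). Rpl7a fell from 132 ± 3.17 to 48.6 ± 0.346 FPKM (2.67-fold, log2 change -1.42, SE 0.09, interval -1.63 to -1.21, limma adjusted p = 8.10e-05). The size of both falls depended on the scaling. Rpl7 had a log2 change of -1.79 with TPM and -0.61 with quantile normalization, and Rpl7a had -2.17 and -1.095. Both Adult libraries were below both P5 libraries for each gene, and both calls held under every alternative and with any library left out. Among the isoforms, the main annotated form of Rpl7a (914 bases) fell by 1.75 on the log2 scale (adjusted p = 0.000286). The main annotated form of Rpl7 (1163 bases) fell by 0.88 (adjusted p = 0.00859) and an unannotated variant of it (956 bases) by 1.38 (adjusted p = 0.00120), while no isoform of either gene was called between E18 and P5. The other tested isoforms, all at lower levels, were not called from P5 to Adult, with log2 changes from -0.28 to 0.20.

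All 46 large subunit and all 33 small subunit genes fell from P5 to Adult (the same numbers when adjusted over each list alone), with medians of -1.21 and -1.26, or -1.14 and -1.19 relative to all genes. Rpl35 went from 184 ± 0.122 to 47.5 ± 2.34 FPKM (log2 change -1.93), Rps19 from 287 ± 8.68 to 71.7 ± 3.21 FPKM (-1.99) and Rplp1 from 453 ± 4.97 to 289 ± 24.0 FPKM (-0.65). Rpl7 ranked 56 and Rpl7a 28 from the lowest of the 79 changes. Relative to all genes, the medians of the large and small subunit were -1.21 and -1.26 with TPM, -0.79 and -0.85 with quantile normalization, and -1.09 and -1.14 with protein-coding genes only. With quantile normalization 43 and 30 of the genes fell, and with protein-coding genes only 45 and 32. camera gave adjusted p = 1.96e-14 and 3.48e-11, and the calls were lost with an estimated correlation (adjusted p = 0.354 for both). fry gave adjusted p = 0.000763 and 0.0011. In the same comparison the median of the RGC markers was -2.90.

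Other genes of translation fell as well. Initiation factors had 33 fallen of 48 (33 when adjusted over the list alone; median -0.57), such as the helicase Eif4a1 (326 ± 40.6 to 96.6 ± 3.33 FPKM, log2 change -1.74). Elongation and termination factors had 7 fallen and 1 risen of 11 (the same over the list alone; median -0.90), such as Eef1a1 (2166 ± 2.32 to 627 ± 4.88 FPKM, -1.79). Ribosome biogenesis had 26 fallen of 47 (26 over the list alone; median -0.38), such as Npm1 (129 ± 8.32 to 69.6 ± 2.93 FPKM, -0.88). Mitochondrial ribosomal proteins had 47 fallen and 1 risen of 75 (the same over the list alone; median -0.50), and paralogs of cytosolic ribosomal proteins had 4 fallen of 5 (median -0.86; 2 fallen without Adult replicate 1). camera called these lists (adjusted p = 9.97e-06, 0.0407, 0.00201, 0.000105 and 0.0471), calls lost with an estimated correlation (adjusted p = 0.354 for all but the mitochondrial list, with 0.465). With protein-coding genes only, 21 initiation factors, 13 biogenesis genes and 28 mitochondrial ribosomal proteins fell, with TPM 44 biogenesis genes fell, and with quantile normalization 2 paralogs fell. These scalings moved all genes as well. Relative to all genes, the medians of initiation factors, elongation factors, biogenesis genes and mitochondrial ribosomal proteins were -0.50, -0.83, -0.31 and -0.42 as deposited, -0.55, -0.90, -0.35 and -0.47 with TPM, and -0.48, -0.77, -0.27 and -0.38 with protein-coding genes only. With quantile normalization initiation factors had -0.32 and paralogs -0.45, against -0.79 for paralogs as deposited. Genes of oxidative phosphorylation had 49 fallen and 4 risen of 76 (50 and 4 over the list alone; median -0.48; camera adjusted p = 6.13e-06, and adjusted p = 0.646 with an estimated correlation). Ndufa1 went from 225 ± 3.54 to 68.3 ± 2.09 FPKM (-1.71) and Sdha from 44.7 ± 3.22 to 105 ± 4.03 FPKM (1.21). Of these, 26 fell and 7 rose with quantile normalization (median -0.17), 30 and 6 with protein-coding genes only (-0.18) and 74 and 1 with TPM (-1.23). Relative to all genes the median was -0.40 as deposited and -0.11, -0.37 and -0.47 in these scalings.

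Axon growth and regeneration genes had 26 fallen and 1 risen of 33 (the same when adjusted over the list alone; median -2.00; camera adjusted p = 7.51e-08, and adjusted p = 0.354 with an estimated correlation). Gap43, a protein of growth cones, went from 1067 ± 57.9 to 34.6 ± 1.47 FPKM (log2 change -4.91), the tubulin Tubb2b from 1063 ± 14.1 to 8.63 ± 1.87 FPKM (-6.80) and Stmn2, a regulator of microtubules, from 535 ± 35.9 to 34.2 ± 3.11 FPKM (-3.93). Among synaptic vesicle and active zone genes, 17 rose and 5 fell of 28 (median 0.80; camera adjusted p = 0.00325, and adjusted p = 0.354 with an estimated correlation). These included Cplx3, a complexin of retinal ribbon synapses and some amacrine cells (0.179 ± 0.0803 to 163 ± 3.202 FPKM, 7.12), and Stx1a (70.8 ± 8.27 to 8.61 ± 0.391 FPKM, -2.90). Postsynaptic receptors and scaffolds had 15 risen and 9 fallen of 37 (median 0.26), without a camera call (adjusted p = 0.113). Sodium and potassium channels had 18 risen and 5 fallen of 28 (median 0.78; camera adjusted p = 0.00102, and adjusted p = 0.354 with an estimated correlation), such as Kcnab1 (2.48 ± 0.267 to 56.2 ± 21.8 FPKM, 3.99). Immediate early genes had 10 risen and 1 fallen of 19 (median 0.60; camera adjusted p = 0.00300, and adjusted p = 0.354 with an estimated correlation), such as Egr1 (3.54 ± 0.5005 to 29.4 ± 12.3 FPKM, 2.69). With TPM, which moved the median of all genes to -0.76, vesicle genes had 9 risen and 9 fallen (median 0.06), channels 11 and 8 (0.06) and immediate early genes 5 and 3 (0.02). These lists held their medians relative to all genes, at 0.87, 0.85 and 0.67 as deposited and 0.82, 0.81 and 0.77 with TPM.

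Of 25 RGC markers, 21 fell and 1 rose from P5 to Adult (the same when adjusted over the list alone; median -2.90; camera adjusted p = 2.56e-06, and adjusted p = 0.359 with an estimated correlation). Pou4f2, a transcription factor of RGCs, went from 98.0 ± 9.94 to 3.11 ± 1.402 FPKM (log2 change -4.63), Isl1 from 126 ± 14.7 to 8.85 ± 0.464 FPKM (-3.68) and Sncg from 659 ± 55.8 to 61.8 ± 35.1 FPKM (-3.51). The marker that rose, chosen after its values were seen, was Ebf4 (log2 change 1.14, adjusted p = 0.000762). Markers of rods had 20 risen of 21 (median 5.38), of cones 9 of 10 (3.09), of bipolar cells 10 of 11 with 1 fallen (2.26), of amacrine cells 14 of 16 with 1 fallen (3.91), of Müller glia 14 of 17 with 1 fallen (2.998), and of astrocytes 4 of 4 (2.40). Only 4 of the 10 astrocyte markers fixed for the list were tested. With protein-coding genes only the bipolar median was 3.79 (3.598 relative to all genes, against 2.33 as deposited). camera called the lists of these 6 cell types (adjusted p = 5.05e-07, 9.97e-06, 0.000247, 2.56e-06, 2.56e-06 and 0.00725), calls lost with an estimated correlation (adjusted p = 0.504, 0.354, 0.354, 0.354, 0.375 and 0.354). The amacrine glycine transporter Slc6a9 went from 3.91 ± 0.332 to 196 ± 41.1 FPKM. Glul of Müller glia went from 98.7 ± 5.98 to 659 ± 60.5 FPKM and the cone opsin Opn1sw from 0.00424 ± 0.00542 to 33.4 ± 3.69 FPKM. Rod markers had a median of 4.25 without Adult replicate 1 (20 risen, 1 fallen) and 6.86 without Adult replicate 2 (20 risen). Horizontal cell markers differed from these, with 3 risen and 3 fallen of 6 (median 0.06, turning to -0.57 with TPM, -0.10 with quantile normalization and -0.01 without P5 library b; relative to all genes 0.13, 0.18 with TPM and -0.04 with quantile normalization).

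**Figure D3:**
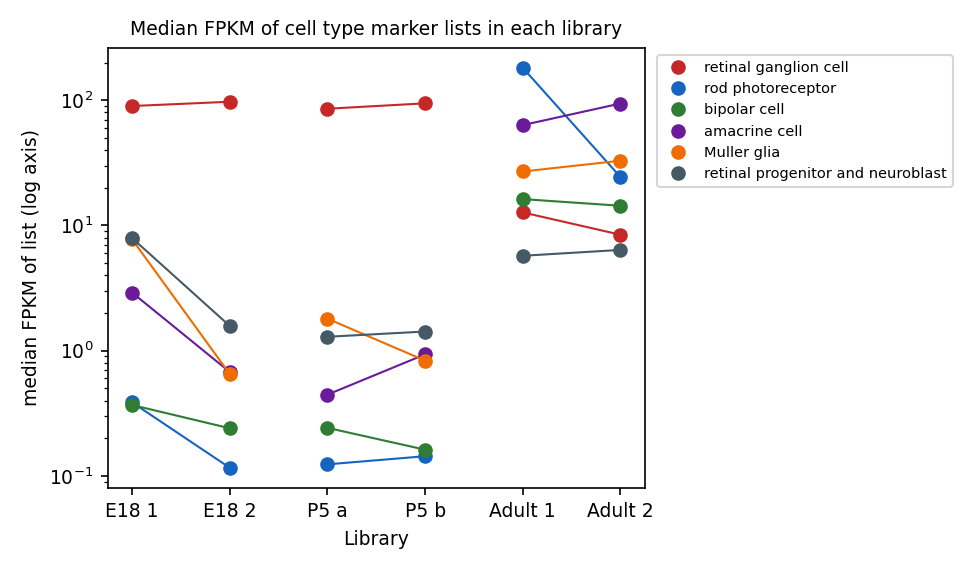
Median FPKM (vertical axis, log scale) of 6 cell type marker lists in each of the 6 libraries; lines join the 2 libraries of an age. RGC markers had medians of 85.5 to 97.2 FPKM in the E18 and P5 libraries and of 12.7 and 8.43 FPKM in the Adult libraries, in which rod markers had 182 and 24.4 FPKM.

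Across all genes, limma called 3767 genes higher and 4843 lower in Adult than at P5 (8610 of 14390; Benjamini-Hochberg). The balance turned with protein-coding genes only (4470 higher, 2961 lower) and widened with TPM (1709 higher, 8603 lower). At isoform level 6704 were higher and 8433 lower, which turned to 8332 and 5729 with protein-coding genes only and widened to 3265 and 15399 with TPM. Among genes not listed at 0 at P5, the largest rises included the rod arrestin Sag (0.135 ± 0.0780 to 367 ± 413 FPKM, log2 change 7.63), Gad1, an enzyme of GABA synthesis (0.899 ± 0.483 to 374 ± 107 FPKM, 7.62), and C1ql1 (0.233 ± 0.103 to 213 ± 63.4 FPKM, 7.41). The largest falls included the neuronal RNA Bc1 (359 ± 164 to 0.978 ± 1.38 FPKM, -7.63), Cd24a (432 ± 20.7 to 2.71 ± 0.319 FPKM, -6.87), Tubb2b and Islr2 (292 ± 56.6 to 3.28 ± 1.18 FPKM, -6.11). Also among them were 5 genes of the RP23-8J15 series, such as RP23-8J15.4 (316 ± 37.7 to 2.36 ± 0.194 FPKM, -6.56).

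Between E18 and Adult, the span of both steps, Rpl7 fell to 143 ± 2.78 FPKM from 496 ± 29.1 FPKM (3.46-fold, log2 change -1.79, SE 0.09, interval -2.02 to -1.56, limma adjusted p = 4.13e-05). Rpl7a fell to 48.6 ± 0.346 FPKM from 185 ± 2.10 FPKM (3.74-fold, log2 change -1.90, SE 0.09, interval -2.11 to -1.69, limma adjusted p = 2.75e-05). All 46 large and all 33 small subunit genes fell, as they did when adjusted over each list alone (medians -1.78 and -1.69, or -1.66 and -1.58 relative to all genes). Rps26 fell furthest (log2 change -2.71, 414 ± 3.03 to 62.7 ± 3.77 FPKM). Rpl13a, chosen after its values were seen, fell least (-0.83). Rpl7 and Rpl7a ranked 35 and 28 from the lowest. camera gave adjusted p = 1.77e-16 and 2.90e-13, calls lost with an estimated correlation (adjusted p = 0.354 for both). RGC markers had 20 fallen and 2 risen of 25 (median -2.68) and rod markers 20 risen of 21 (median 5.56) over the same span.

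Most axon growth genes fell over the whole span, and more synaptic and channel genes rose than fell. Axon growth and regeneration genes had 28 fallen and 2 risen of 33 (29 and 2 when adjusted over the list alone; median -2.27). Gap43 stood at 1426 ± 146 FPKM at E18 and 34.6 ± 1.47 FPKM in Adult (log2 change -5.32). Sodium and potassium channels had 21 risen and 3 fallen of 28 (21 and 5 over the list alone; median 1.65), such as Kcna1 (1.014 ± 0.310 to 25.5 ± 5.73 FPKM, 3.71). Synaptic vesicle genes had 20 risen and 4 fallen of 28 (the same over the list alone; median 1.09), such as Syp (93.5 ± 5.26 to 361 ± 14.7 FPKM, 1.94). Postsynaptic genes had 21 risen and 4 fallen of 37 (the same over the list alone; median 0.68). camera called these lists (adjusted p = 1.92e-09, 3.37e-06, 9.26e-05 and 0.000481), calls lost with an estimated correlation (adjusted p = 0.354, 0.354, 0.354 and 0.474). With TPM, vesicle genes had 15 risen and 7 fallen (median 0.48), postsynaptic genes 13 and 12 (0.07) and channels 20 and 6 (1.13). Relative to all genes, whose median moved to -0.68, these lists had 1.20, 0.79 and 1.76 as deposited and 1.16, 0.75 and 1.805 with TPM. Markers of amacrine cells (14 of 16 risen, median 3.38) and bipolar cells (10 of 11, 2.94) rose over the same span, so the values do not tell in which cells the synaptic and channel genes rose. Cholesterol synthesis had 16 fallen and 1 risen of 21 (median -1.20; camera adjusted p = 0.00391, and adjusted p = 0.705 with an estimated correlation), with 9 fallen without E18 replicate 2 and 8 without Adult replicate 1. Nuclear genes of oxidative phosphorylation had 28 fallen and 4 risen of 76 (14 and 21 with quantile normalization, 15 and 25 with protein-coding genes only, 67 and 1 with TPM). Their median was -0.25, which turned to 0.09 with quantile normalization and 0.10 with protein-coding genes only (relative to all genes -0.14, turning to 0.17 and staying at -0.11; camera adjusted p = 0.0525; 18 fallen without E18 replicate 2).

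Across all genes, limma called 3638 genes higher and 4950 lower in Adult than at E18 (8588 of 14390; Benjamini-Hochberg). The balance turned with protein-coding genes only (4704 higher, 2912 lower) and widened with TPM (2047 higher, 8138 lower). The largest falls included Cd24a (951 ± 128 to 2.71 ± 0.319 FPKM, log2 change -7.998), Tubb2b (-7.20), the imprinted gene Nnat (1248 ± 98.1 to 14.5 ± 1.52 FPKM, -6.33) and Sox11 (126 ± 2.20 to 0.768 ± 0.202 FPKM, -6.17). The largest rises included Gnat1, the rod transducin (0.146 ± 0.0805 to 397 ± 442 FPKM, 7.75), and C1ql2 (0.0697 ± 0.000134 to 147 ± 44.9 FPKM, 7.08). Isoforms numbered 6241 higher and 9370 lower, which turned to 7921 and 5831 with protein-coding genes only and widened to 3622 and 15629 with TPM, with 8497 called in all without E18 replicate 1 and 7843 without E18 replicate 2.

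Genes that changed one way in both steps numbered 280 that fell and 253 that rose. Lists of the same sizes drawn independently would share 240 and 208. Another 340 rose then fell and 236 fell then rose (268 and 186 for independent lists). Of the 280 genes that fell in both steps, 53 were cytosolic ribosomal protein genes, Rpl7 and Rpl7a among them. Simulated unchanged groups gave 0 such genes on average over 50 simulations. Hardly any gene is called in such groups, so this count was near 0 in advance and does not bear on the overlap. The P5 libraries enter both steps, which pulls the changes of the steps apart (covariance across genes -0.07, and -0.05 in simulated unchanged groups). They were not split between the steps, since each step would have kept 1 P5 library. The sum of both directions, 533 genes, was 5, 18, 4, 175, 244 and 230 without E18 replicate 1, E18 replicate 2, P5 library a, P5 library b, Adult replicate 1 and Adult replicate 2.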

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

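The rescaling to protein-coding genes and the fit without genes listed at 0 in an age were chosen after the results were seen; the other alternatives were planned. Rpl7 and Rpl7a kept lower values at the later age in every alternative, and their calls from P5 to Adult (highest adjusted p 0.00560 and 0.000791) and from E18 to Adult (0.00353 and 0.00328) held in all of them and with any library left out. The log2 changes themselves moved with the alternatives for values and fit. From P5 to Adult they ranged from -1.79 to -0.61 (Rpl7) and from -2.17 to -1.095 (Rpl7a). From E18 to Adult the ranges were -2.41 to -1.295 and -2.53 to -1.497. From E18 to P5, Rpl7a lost its call with TPM (-0.35, adjusted p = 0.0541), without the trend (-0.49, 0.0537) and with the most abundant isoform (-0.45, 0.0594), and Rpl7 with the most abundant isoform (-0.71, 0.0610). Over the alternatives their adjusted p ranged from 0.0194 to 0.0594 and from 0.00364 to 0.0610; the cause was not tested. With 1 library left out, Rpl7a was called from E18 to P5 in none of the 6 fits (highest adjusted p 0.190, without E18 replicate 1), and Rpl7 lost its call in 3 (highest 0.108). The medians of the large and small subunit lists did not move with the estimated correlation (-0.47, -0.57, -1.21, -1.26, -1.78 and -1.69). The camera adjusted p became 0.354 in all 3 comparisons, with estimated correlations of 0.23 and 0.35. Lists whose estimate lay below the preset of 0.01 lost their calls as well, such as astrocyte markers (-0.04) from P5 to Adult. The size of the estimated correlation therefore does not by itself account for the lost calls. Bipolar markers, with an estimate of 0.016, went from an unadjusted camera p of 7.02e-05 to 0.0305 from P5 to Adult. With an estimated correlation camera tests on the 3 residual degrees of freedom of the fit, which leaves it little power. Over the other alternatives the camera adjusted p of the subunit lists went as low as 3.25e-20 and 7.96e-18 from E18 to P5.

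Called genes from E18 to P5 were 696 with only the 4 libraries compared, 513 with a 2-fold minimum and 961 with the most abundant isoform; the 2-fold minimum gave 4306 from P5 to Adult and 4534 from E18 to Adult. Called isoforms from E18 to P5 were 331 and 270 with pseudocounts of 0.1 and 0.01, 306 with no filter, 1040 with a mean of at least 5 FPKM, 1065 with TPM, 171 without the trend and 5 with only the 4 libraries compared. With a mean of at least 5 FPKM, 7640 isoforms were called from P5 to Adult and 7707 from E18 to Adult. Genes changed one way in both steps were 240 with the 4 libraries of each comparison, 111 with a 2-fold minimum and 315 with the most abundant isoform. Fewer libraries, fewer isoforms tested or an added minimum account for part of these; for the rest the cause was not tested.

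With 1 library left out in turn, a lone library being assumed to vary like the others, called genes ranged from 10 to 642 (E18 to P5), 7374 to 7777 (P5 to Adult) and 6138 to 8782 (E18 to Adult), and isoforms from 3 to 18, 10696 to 13154 and 7843 to 15009. Genes changed one way in both steps ranged from 4 to 244. Rpl7 ranged from -0.81 to -0.69, -1.07 to -1.004 and -1.85 to -1.73, and Rpl7a from -0.51 to -0.46, -1.44 to -1.39 and -1.92 to -1.89. The subunit lists kept their camera calls in these fits.

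Of 588 results of named genes, 463 were called. TPM lost 23 of these calls, quantile normalization 24, the fit without the trend 19 and that with the 4 libraries 46; left-out libraries lost between 54 (Adult replicate 2) and 110 (E18 replicate 1, P5 library a), and each other alternative lost 7 or fewer. A single called gene turned direction: Ccne2, Adult against E18, had -0.01477 with TPM (adjusted p = 0.941; over its alternatives from 0.00447 to 0.941), which moved the median of all genes to -0.68. E18 and Adult libraries share replicate numbers, and the replicate differences of these ages did not run together (r = 0.018 across 14390 genes). With that number as a block, limma called 8056 genes and 12464 isoforms between E18 and Adult. The deposited FPKM give no depth, so no limit from counting can be stated.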

Other observations

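Of the tests on explanations given here, those of transcript length from E18 to P5 and of the spread of RGC markers were set before their results were seen and the others after. In all 14 tests were tried, of which 3 were replaced by others and 3 left out once their results were known. Intervals in these tests come from resampling genes 2000 times. They treat genes as independent and do not measure the spread between libraries.

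Immune, stress and signaling lists held genes that moved in opposite directions from P5 to Adult, with a balance that depended on the scaling. With TPM, which moved the median of all genes to -0.76, risen and fallen genes numbered 3 and 4 (interferon), 2 and 14 (heat shock), 0 and 12 (mTOR), 2 and 13 (splicing), 8 and 20 (guidance) and 1 and 10 (neurofilaments). With protein-coding genes only they numbered 7 and 0, 7 and 5, 7 and 3, 7 and 8, 15 and 12, and 5 and 8. Interferon and MHC class I genes had 4 risen and 1 fallen of 11 (median 0.39, turning to -0.06 with TPM; relative to all genes 0.47 and 0.70). None fell without E18 replicate 1, E18 replicate 2 or P5 library a, and 2 fell without Adult replicate 2. H2-K1, an antigen-presenting molecule, went from 0.563 ± 0.0863 to 14.7 ± 1.66 FPKM. Heat shock and unfolded protein genes had 7 risen and 8 fallen of 22 (median -0.24, turning to 0.08 with protein-coding genes only; relative to all genes -0.17 and -0.11, turning to 0.03 with quantile normalization; 3 risen without Adult replicate 1). The mTOR pathway had 5 risen and 6 fallen of 16 (median -0.09, turning to 0.09 with quantile normalization and 0.23 with protein-coding genes only; relative to all genes -0.02, 0.15 and 0.03; 3 fallen without either Adult replicate 1 or 2). In it Akt1 fell (87.1 ± 7.82 to 35.1 ± 1.23 FPKM) and Rptor rose (8.56 ± 0.774 to 17.6 ± 0.158 FPKM).

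Splicing regulators of neurons had 6 risen and 8 fallen of 20 (median -0.11, turning to 0.21 with protein-coding genes only, 0.07 without P5 library a and 0.09 without Adult replicate 1). Their median relative to all genes was -0.04 as deposited, 0.05 with quantile normalization and 0.02 with protein-coding genes only. Elavl2 fell among them (62.6 ± 8.35 to 9.06 ± 1.53 FPKM). Axon guidance genes had 12 risen and 15 fallen of 36 (median -0.02, turning to 0.29 with protein-coding genes only, 0.02 without P5 library b and 0.04 without Adult replicate 1). Their mean was negative too (-0.01), while relative to all genes their median was 0.05 (0.10 with protein-coding genes only) and the direction of camera was up, without a call (adjusted p = 0.971). Nrp1 fell (39.3 ± 4.88 to 4.05 ± 0.331 FPKM) and Slit2 rose (log2 change 2.74). Neurofilament and axon cytoskeleton genes had 9 fallen and 4 risen of 15 (median -0.95; camera adjusted p = 0.179), with Nefl at 1025 ± 168 FPKM at P5 and 87.2 ± 53.5 FPKM in Adult. Of 10 mitochondrially encoded genes (median -1.96; camera adjusted p = 0.378), mt-Atp6, mt-Atp8, mt-Co3 and mt-Nd3 were listed at 0 in both Adult libraries, which is not read as a fall here. Of the other 6, 2 fell and 3 rose, and their median was positive (0.38); mt-Co1 went from 5465 ± 458 to 2826 ± 643 FPKM.

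Among cells outside the neural retina, endothelial markers had 3 risen of 3 from P5 to Adult (median 2.77), those of the retinal pigment epithelium 2 of 2 (3.35), lens 2 of 2 (2.58) and pericytes 1 of 2 (1.04). Few of the markers fixed for these lists were tested: 3 of 14 endothelial, 2 of 12 pigment epithelium, 2 of 16 lens and 2 of 10 pericyte markers. A marker near 0 at E18 and P5 is tested only if it is high in Adult, so these counts lean towards rises. Fibroblast markers had 1 risen and 1 fallen of 2 (0.10, turning to -0.64 with TPM and -0.12 without Adult replicate 2; relative to all genes 0.18 and 0.12 with TPM). The oligodendrocyte lineage had 2 fallen of 4 (-0.43; 1 fallen without Adult replicate 1). The erythrocyte gene Hbb-bs had 12.1 FPKM in E18 replicate 1 and 0.289 FPKM in replicate 2 and was not called from P5 to Adult (0.01, turning to -0.03 with TPM and -0.06 with quantile normalization). The T lymphocyte gene Lck fell (4.77 ± 0.386 to 0.421 ± 0.102 FPKM). Of 19 microglia and macrophage markers, 2 were listed among the deposited genes and none was tested. E18 replicate 1 exceeded replicate 2 by a median of 0.49 for amacrine markers and 0.34 for Müller glia markers.

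Cytosolic ribosomal protein genes were lower at P5 than at E18. Poorer recovery of short transcripts, as the whole cause, is argued against by a difference of -0.4732 (interval -0.55 to -0.42) from the nearest genes by length and level, which changed by 0.01. The match was loose (those genes differed by 0.63 in log2 length and -0.66 in log2 level), so it does not exclude a part. Other protein-coding genes of at least 20 FPKM had medians of 0.08 up to 1000 bases and 0.003 above, so short transcripts did not fall in general. Among the ribosomal protein genes the slope per doubling of length was 0.03 (interval -0.03 to 0.09), which leaves room only for a small part. Reads shared with pseudogenes, as the whole cause, are argued against by the change of -0.5095 (interval -0.60 to -0.43) that a regression over the 79 genes gives at no shared sequence; the test it replaced gave -0.44 (interval -0.54 to -0.35) against genes that shared 26.2 percentage points less and so were poorly matched. A smaller share of RGCs at P5, as the whole cause, is argued against by the median change of their markers, 0.05318. Its interval (-0.17 to 0.79) lies above the ribosomal protein median of -0.51. The markers went both ways, however, with an SD of 0.83, wider than their distance of 0.56 from that median. The bound of this test was therefore not met, and a smaller share as part of the cause cannot be told apart from a fall within RGCs. The age of the animals may account for the pattern and was not tested.

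The same genes were lower in Adult than at P5. Length as the whole cause is argued against by a slope of 0.01905 per doubling of length (interval -0.13 to 0.17). This test and its bound of 0.4 were chosen after the first one, a difference of -0.43 (interval -0.54 to -0.19) from the nearest genes by length and level, met neither of its bounds. Those genes had -0.85 and were longer by 0.42 in log2, but they were matched on level as well. Among other protein-coding genes of at least 20 FPKM, the median was -0.56 up to 1000 bases and -0.38 above, so length could account for part. Pseudogenes as the whole cause are argued against by a change of -1.36 (interval -1.62 to -1.13) at no shared sequence, chosen after a poor match (23.6 percentage points less sharing) gave an undecided -0.44 (interval -0.55 to -0.32); other genes with at least 50% shared sequence had -0.63 and those under 1% had -0.05, so part may come from them. Other cell types with fewer ribosomal protein transcripts cannot be told apart from a fall within RGCs, because the RGC markers changed by -2.902 (interval -3.68 to -1.75) in the same libraries. Adult replicate 1 exceeded replicate 2 by a median of 2.91 in log2 for rod markers, and by 0.08 and 0.14 for the large and small subunit. More rod RNA thus did not come with lower ribosomal protein values. RGC markers differed by 0.71, and amacrine and Müller glia markers by -0.45 and -0.28, so other cells stay open. Age was not tested apart from these, nor from other differences of the Adult libraries, such as their higher share of small RNAs.

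RGC markers were lower in Adult, and markers of rods, cones, bipolar cells, amacrine cells and Müller glia were higher, but not those of horizontal cells as a list. RNA of rods may account for the rises of rod genes: these 21 genes had a median ratio of 7.67 between the Adult libraries (Gnat1 710 and 84.5 FPKM), with an SD of the log2 ratios of 0.688, close to the bound of 0.7 set after the result was seen, although Gnb1 and Gnb3 of that list are not specific to rods. The medians of cone, bipolar, amacrine and Müller glia markers differed by 0.01, -0.11, -0.45 and -0.28 in log2 between these libraries, so the rises of these lists stay open, and sorting adult RGCs with those cells removed would test it. A lower share of RGCs as the whole cause of the marker fall cannot be told apart from changes within RGCs, because the SD of the marker changes, 1.633, has an interval (1.20 to 1.99) that spans its bound of 1.4. Age was not tested apart from the share of cells, nor from other differences of the Adult libraries, such as their higher share of small RNAs.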
